A study of Mus musculus with 12 samples.

How the data were processed

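MicroRNA abundance was measured on a NanoString nCounter mouse miRNA panel, which counts single fluorescent barcodes bound to each target without amplification. The samples were total RNA from mHypoE-46, an immortalised embryonic mouse hypothalamic neuronal line that expresses neuropeptide Y and agouti-related peptide. Cells received vehicle, which was phosphate buffered saline, or 100 nM insulin for 4 h or 24 h. The 4 groups held 3 replicates each, 12 libraries in all.

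The deposited raw table holds digital counts of 620 probes per library. It was read as an expected count table because header values of the instrument in the same columns of the deposited file are not whole; every probe value was a whole number, so rounding changed nothing. The design fixed before the data were examined had assumed plain counts, and the test was run on these whole counts. The authors also deposited a processed signal table. In it, each signal of a mouse miRNA or housekeeping probe equals the raw count times 1 factor per lane. That factor matched the inverse geometric mean of the 100 mouse miRNA probes of highest mean count, with a largest relative gap of 0.00041%. For control and viral probes, 600 of 600 deposited signals equal the raw count. The software that made the signals is not given in the sources used here. Names of miRNAs are those of the probe table, and no genome build is named there, so no coordinates are given.

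The panel held 566 mouse miRNA probes, 33 viral miRNA probes, 8 negative controls, 6 positive controls, 3 spike-in probes and 4 housekeeping mRNAs. A mouse miRNA was tested when its count lay above its library's negative control mean plus 2 SD in at least 3 of 12 libraries. This kept 195 miRNAs, 34.5% of the mouse probes. The same filter was met by 5 of the 33 viral probes, so meeting it does not by itself show that a miRNA was present. Viral, control and housekeeping probes stayed outside the tests. Probes named miR-20a+miR-20b and miR-106a+miR-17 each read a pair of miRNAs together. Members of the let-7 family are near identical in sequence, so values of single members are uncertain. Each library's total and negative control threshold set its precision.

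Counts were analysed in edgeR 4.0.16 under R 4.3.3 with TMM scaling and the quasi-likelihood F test, two-sided, with the 4 groups in one fit. The fit had 8 residual degrees of freedom and 6.77 prior degrees of freedom. The contrasts were insulin against vehicle at 4 h and at 24 h, the difference between those responses, their mean, and 24 h against 4 h in vehicle and in insulin. A Benjamini-Hochberg adjusted p under 0.05 over the 195 miRNAs counted as a call. A further contrast, 24 h against 4 h averaged over both treatments, was added after the data were seen. Fold changes are log2 values with their standard error (SE). Abundance is in CPM, the usual depth-scaled count of edgeR after TMM scaling, as mean ± SD of 3 libraries. An interval is a 95% confidence interval. This fit did not subtract background, which pulls fold changes and intervals of miRNAs with low counts towards no change.

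A set of 10 miRNA lists was fixed before the data were examined: the let-7/miR-98 family, reported regulators of insulin signalling and glucose metabolism, neuron-enriched miRNAs, stimulus- and activity-responsive miRNAs, the miR-17-92 and paralogous clusters, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 intronic cluster families, the epithelial miR-200 and miR-183 families, a glial and mesenchymal list, and a blood, endothelial, liver and muscle list. The last 3 stand for other cell types or serum. Only members that passed the count filter were tested: 9 of 9 let-7 probes on the panel, 29 of 37 insulin regulators and 13 of 30 neuron-enriched. Further lists had 15 of 21 stimulus-responsive, 8 of 11 miR-17-92, 11 of 62 Dlk1-Dio3 and 5 of 33 Sfmbt2 probes. The last 3 had 4 of 10 epithelial, 8 of 15 glial and mesenchymal and 6 of 19 blood probes. List results therefore cover the tested members, not each whole cluster. Each list was tested with limma 3.58.1 camera (preset correlation 0.01, and an estimated correlation) and fry on log2 CPM with a prior count of 2, for the 4 h response, the 24 h response and their difference, with adjustment over 30 tests. The lists share members, and miR-1983 entered the list of insulin regulators and the named miRNAs from knowledge of this study, so it is not independent evidence.

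The named miRNAs followed a rule fixed before the data were examined. For the insulin contrasts and their difference it takes up to 10 called miRNAs per direction, or the 5 of smallest p where fewer than 5 passed. For the averaged and time contrasts it takes up to 5 per direction. It adds miR-1983, let-7 members, miR-132, miR-212, miR-124, miR-9, miR-7a, miR-103, miR-107, miR-143, miR-145 and miR-29a to miR-29c, the 10 most abundant miRNAs, and 2 to 4 members of each list.

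The pipeline was tested on simulated data made from the fitted means and spread: 20 data sets with 40 of 195 miRNAs changed. At a 2-fold change it recovered 86.9% of them in the 4 h response, 86.5% in the 24 h response and 50.4% in their difference. At 1.5-fold the shares were 34.3%, 36.1% and 7.86%. Of the calls in these 3 contrasts, 3.65%, 3.48% and 6.07% were false. For 24 h against 4 h, a 1.5-fold change was recovered for 37.1% in vehicle and 36.4% in insulin. All these changes were made in the whole count, background included, so the shares may be too high for miRNAs near background. A 1.5-fold shift of the let-7 list was found in 20 of 20 sets at 4 h, 20 at 24 h and 17 for the difference, and in 15, 17 and 11 with an estimated correlation. With nothing shifted, the 20 sets made beside each of these had any of the 30 list tests called in 0, 2 and 0 sets. Simulated miRNAs were drawn independently of each other, whereas the let-7 list had an estimated correlation of 0.65 in the real data. The shares of list shifts found and of false list calls therefore do not carry over to lists with correlated members.

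Alternatives were DESeq2 1.42.0, scaling to the 100 most abundant miRNAs, to housekeeping mRNAs or to positive controls, subtraction of the negative control mean, no filter, a mean count of at least 100, limma on the authors' signals with a pseudocount of 1 or 10, only the groups compared, the replicate number as a block, and leaving out each library. A lane covariate, and leaving out the pair of libraries with the lowest mean correlation with their group, were added after the data were seen. Whether replicate numbers pair libraries was checked from the correlation of same-numbered deviations from the group means across miRNAs. At 24 h the insulin and vehicle libraries of numbers 1, 2 and 3 had r of 0.59, 0.50 and 0.31. For number 3 the highest r with another number was 0.309, against 0.306 with its own. Same-numbered libraries also lay in adjacent lanes, so pairing by number at 24 h is possible but cannot be told apart from lane. The labels describe independent repeats of the experiment. The other comparisons had at least 1 r under 0.1. Figures were drawn with matplotlib 3.10.9.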

Results

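MicroRNA counts were obtained from 12 libraries of mHypoE-46 hypothalamic neurons, 3 for each of vehicle at 4 h, insulin at 4 h, vehicle at 24 h and insulin at 24 h. The labels set insulin treatment against insulin resistance, with 4 h as the early and 24 h as the prolonged exposure. Counts of mouse miRNAs per library totalled 142158, 156980 and 213462 for vehicle at 4 h (replicates 1, 2 and 3) and 171622, 210310 and 196814 for insulin at 4 h. At 24 h they totalled 180539, 269357 and 250474 for vehicle and 142491, 379809 and 221668 for insulin. The negative control threshold lay between 38.9 and 124 counts, and 118 to 201 miRNAs per library exceeded it. All 4 h libraries were in lanes 1 to 6 of the cartridge and all 24 h libraries in lanes 7 to 12, so time cannot be told apart from lane block. Within each time point the replicate number ran with the lane, with each vehicle library 1 lane before its insulin partner.

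Averaged over the 12 libraries, the most abundant miRNAs were miR-720, at a mean of 113959 CPM, and miR-125b-5p, a miRNA enriched in brain, at 108406 CPM. They were followed by miR-29b (56643 CPM), let-7c (53339 CPM), miR-21 (48989 CPM), miR-16 (45695 CPM), miR-29a (39599 CPM), miR-22 (30366 CPM), miR-125a-5p (29400 CPM) and let-7b (29082 CPM). The order differed between groups: in vehicle at 4 h, miR-125b-5p (110088 CPM) lay above miR-720 (105441 CPM), and miR-29b (30289 CPM) below miR-21 (45255 CPM) and let-7c (37663 CPM). The probe called miR-720 reads a fragment of a transfer RNA rather than a true miRNA. Of the neuronal miRNAs, miR-9 was above the threshold in 12 of 12 libraries, with 879 to 1916 counts. In contrast, miR-124 (17 to 95 counts) and miR-212 (14 to 31 counts) were above it in 0 libraries and were not tested. The 10 most abundant miRNAs of each library took 49.3% to 55.2% of its counts. The first principal component held 46.7% of the variance, and replicates of 1 group correlated across miRNAs with r of 0.958 to 0.995. The mean r with the other replicates was lowest for insulin 24 h replicate 1 (0.960), followed by vehicle 4 h replicate 1 (0.971) and replicate 3 (0.973). Differences between replicates exceeded counting error in each pair, with a chi-square per degree of freedom of 2.65 to 72.2.

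The comparison of insulin with vehicle at 4 h asks which miRNAs respond before resistance develops. The fitted log2 fold changes (SE, 3 libraries per group) were small. The probes of smallest p with values above 0 were miR-193 at 0.42 (SE 0.19), miR-24 at 0.39 (SE 0.18), miR-297c at 0.62 (SE 0.31), miR-324-5p at 0.31 (SE 0.17) and miR-1944 at 0.39 (SE 0.22). Those below 0 were miR-3472 at -0.45 (SE 0.20), miR-421 at -0.30 (SE 0.15), miR-328 at -0.47 (SE 0.25), miR-193b at -0.36 (SE 0.20) and miR-181a at -0.26 (SE 0.16). For example, miR-24 was at 4695 ± 518 CPM in vehicle and 6143 ± 629 CPM in insulin. None of these passed the test. Among miRNAs with reported roles in insulin action, miR-103 had 0.34 (SE 0.27), miR-107 0.25 (SE 0.17), miR-143 0.33 (SE 0.27), miR-145 0.01 (SE 0.17), miR-29a -0.03 (SE 0.23), miR-29b 0.29 (SE 0.36) and miR-29c 0.03 (SE 0.20). The values of miR-145 and miR-29c were below 0 with scaling to the 100 most abundant miRNAs or to positive controls. The value of miR-1983 was 0.18 (SE 0.20), of activity-responsive miR-132 0.15 (SE 0.21), of miR-7a -0.10 (SE 0.19) and of miR-9 -0.08 (SE 0.19). In edgeR 0 of 195 miRNAs passed, with a smallest adjusted p of 0.971 and 3 at an unadjusted p under 0.05, where chance gives 9.75. DESeq2 called 0 (5 at an unadjusted p under 0.05), and limma on the authors' signals called 0 (2). In counts with background included, the interval excluded a 2-fold change for 178 miRNAs and a 1.5-fold change for 79.

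Of the lists at 4 h, members of the miR-17-92 and paralogous clusters, which promote proliferation, lay above 0 for 6 of 8, with miR-19b at 0.33 and miR-18a at 0.33. The let-7/miR-98 family lay above 0 for 6 of 9 (let-7c 0.37, let-7e 0.24; median 0.18), and above 0 in its median under each scaling tried. Reported regulators of insulin signalling lay above 0 for 20 of 29 (miR-24 0.39, miR-221 0.28), but for 11 with scaling to the 100 most abundant miRNAs or to positive controls. Stimulus-responsive miRNAs lay above 0 for 9 of 15 (miR-221 0.28, miR-181a -0.26), but for 5 under those scalings. Neuron-enriched miRNAs lay above 0 for 5 of 13 (miR-338-5p 0.21, miR-132 0.15), the Dlk1-Dio3 cluster for 5 of 11 (miR-376a 0.40, miR-544 0.35) and the Sfmbt2 families for 3 of 5 (miR-297c 0.62, miR-466d-3p 0.13). Markers of other cell types lay above 0 for 1 of 4 in the epithelial list (miR-96 0.03, miR-200b -0.12), 5 of 8 in the glial and mesenchymal list (miR-143 0.33, miR-338-5p 0.21; 3 of 8 under the same scalings) and 1 of 6 in the blood list (miR-133a -0.28, miR-206 -0.19). None of the lists passed: adjusted camera p values ran from 0.267 to 0.883, with an adjusted p of 0.954 with an estimated correlation and 0.996 by fry. The unadjusted camera p was 0.0178 for the miR-17-92 clusters (p = 0.246 with an estimated correlation) and 0.0422 for the insulin regulators (p = 0.372 with an estimated correlation). In the log2 CPM fit of the list tests, the median (-0.04) and camera direction of the Dlk1-Dio3 cluster were below 0 and the mean was 0.02. Adjusted over the list alone, 0 members of each list passed, as over all 195 miRNAs. Without insulin 4 h replicate 1, the let-7 list was called higher at 4 h (median 0.49 in the log2 CPM fit, where it was 0.15 with all libraries; adjusted camera p = 0.00662, adjusted p = 0.747 with an estimated correlation). Its adjusted p ran from 0.00662 to 0.996 over the alternatives.

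**Figure D1:**
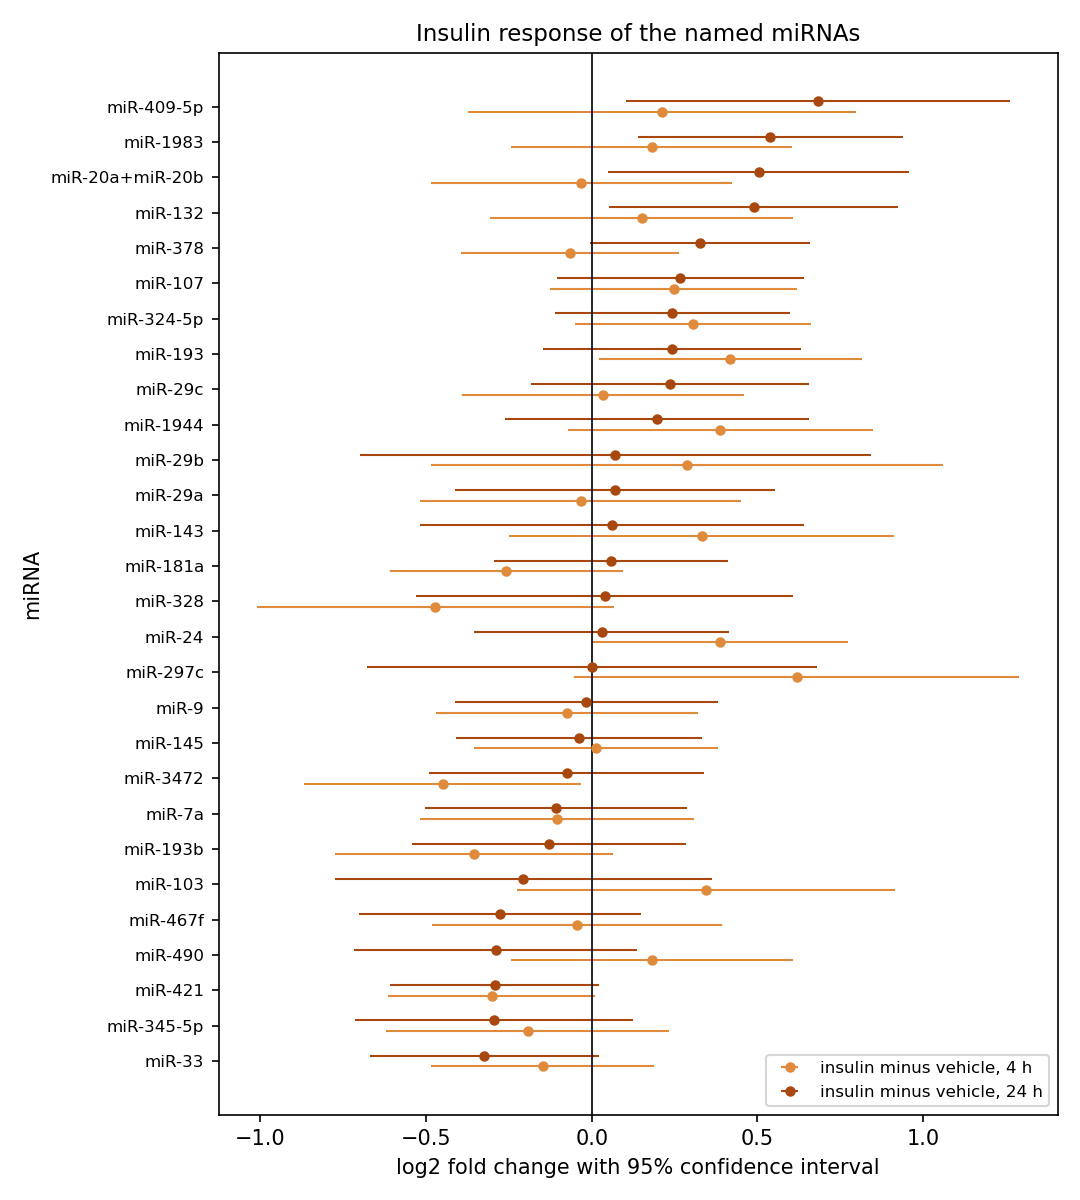
Log2 fold change (insulin over vehicle) of 28 named miRNAs at 4 h and at 24 h on the x axis, with points for the edgeR estimate and bars for its 95% confidence interval (3 libraries per group). No miRNA passed an adjusted p of 0.05 at either time. With housekeeping scaling the 24 h values shift by a median of -0.39. Among the values this puts below 0 are those of miR-107, miR-143, miR-29a, miR-29b, miR-29c and miR-378.

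At 24 h, the time the labels tie to insulin resistance, the miRNA of smallest p was miR-1983, at 450 ± 28.1 CPM in vehicle and 645 ± 149 CPM in insulin (n = 3 each). Its log2 fold change was 0.54 (SE 0.19, interval 0.14 to 0.94), above 0 in 3 of 3 pairs of the same number. Next came miR-409-5p of the Dlk1-Dio3 cluster at 0.68 (SE 0.27), activity-responsive miR-132 at 0.49 (SE 0.20), the proliferation-linked miR-20a+miR-20b at 0.50 (SE 0.21) and miR-378 at 0.33 (SE 0.16). Below 0 were miR-33, which lies within a sterol regulator gene and represses cholesterol export, at -0.32 (SE 0.16), miR-421 at -0.29 (SE 0.15), miR-345-5p at -0.29 (SE 0.20), miR-490 at -0.29 (SE 0.20) and miR-467f at -0.28 (SE 0.20). None of these passed the test. The adjusted p of miR-1983 was 0.962. Its counts were low, between 48 and 230, and above the negative control threshold in 8 of 12 libraries. Those of miR-132 were low as well, between 48 and 219, and above that threshold in 10 of 12 libraries. The values of the other miRNAs with reported roles in insulin action were 0.27 (SE 0.17) for miR-107, -0.21 (SE 0.27) for miR-103, 0.06 (SE 0.27) for miR-143, -0.04 (SE 0.17) for miR-145, 0.07 (SE 0.23) for miR-29a, 0.07 (SE 0.36) for miR-29b and 0.24 (SE 0.20) for miR-29c. Neuronal miR-9 had -0.02 (SE 0.19) and miR-7a -0.11 (SE 0.18). In edgeR 0 of 195 miRNAs passed, with a smallest adjusted p of 0.962 and 4 at an unadjusted p under 0.05. DESeq2 called 0 (6 at an unadjusted p under 0.05), and limma on the authors' signals called 0 (1). In counts with background included, the interval excluded a 2-fold change for 185 miRNAs and a 1.5-fold change for 85. Scaling to housekeeping mRNAs shifted the median of all miRNAs by -0.39 and left miR-1983 at 0.09, miR-132 at 0.01 and miR-20a+miR-20b at 0.07. Without insulin 24 h replicate 2, the largest library, miR-1983 was at 0.32, miR-132 at 0.34 and miR-20a+miR-20b at 0.25.

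Among the lists at 24 h, the let-7/miR-98 family lay above 0 for 9 of 9 members (miR-98 0.46, let-7d 0.36) and the miR-17-92 clusters for 8 of 8 (miR-20a+miR-20b 0.50, miR-106a+miR-17 0.23), but each for 1 member with housekeeping scaling. Neuron-enriched miRNAs lay above 0 for 10 of 13 (miR-132 0.49, miR-218 0.33), stimulus-responsive miRNAs for 12 of 15 (miR-132 0.49, miR-34b-5p 0.31) and reported regulators of insulin signalling for 20 of 29 (miR-1983 0.54, miR-378 0.33), again each for 1 member with housekeeping scaling. The Dlk1-Dio3 cluster lay above 0 for 5 of 11 (miR-409-5p 0.68, miR-136 0.40) and the Sfmbt2 families for 2 of 5 (miR-467f -0.28, miR-466d-3p -0.19). Markers of other cell types lay above 0 for 1 of 4 in the epithelial list (miR-96 -0.15, miR-200c -0.17), 7 of 8 in the glial and mesenchymal list (miR-338-5p 0.16, miR-27a 0.12) and 4 of 6 in the blood list (miR-206 0.23, miR-126-3p 0.13); the last pair lay above 0 for 0 members with housekeeping scaling. None of the lists passed: adjusted camera p values ran from 0.360 to 0.853, with an adjusted p of 0.954 with an estimated correlation and 0.996 by fry. The unadjusted p was 0.0480 by camera for the Sfmbt2 families (p = 0.192 with an estimated correlation) and 0.0378 by fry for the neuron-enriched list. In the log2 CPM fit, the median (-0.06) and camera direction of the Dlk1-Dio3 cluster were below 0 and the mean was 0.00. Adjusted over the list alone, 0 members of each list passed, as over all 195 miRNAs. Without insulin 24 h replicate 1, the Sfmbt2 families were called lower at 24 h (median -0.29 in the log2 CPM fit, where it was -0.11 with all libraries; adjusted camera p = 0.00467, adjusted p = 0.300 with an estimated correlation). Their adjusted p ran from 0.00455 to 0.996 over the alternatives.

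**Figure D2:**
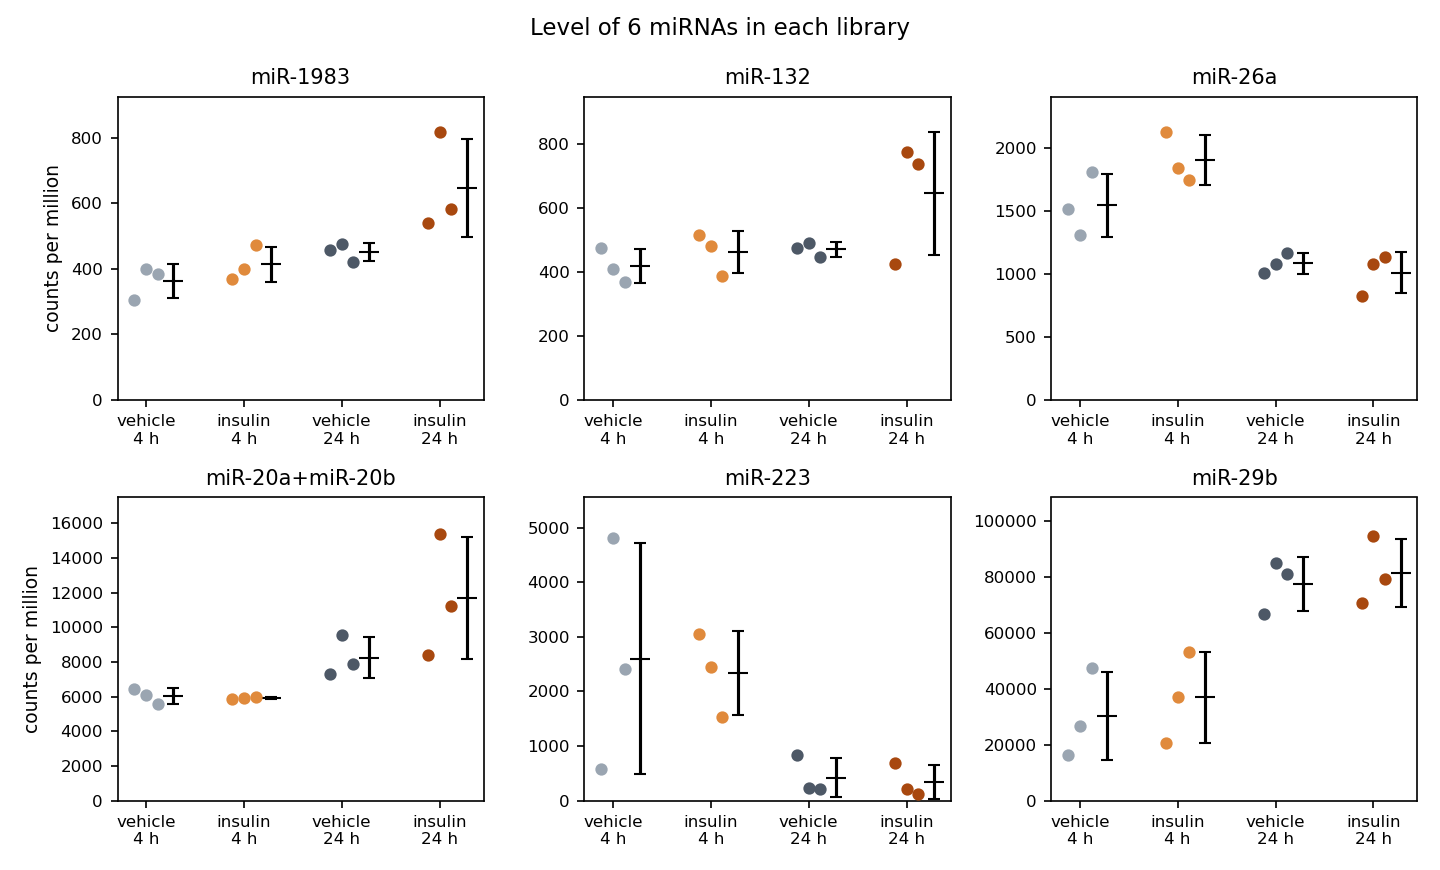
Abundance in CPM (y axis, TMM scaling) of miR-1983, miR-132, miR-26a, miR-20a+miR-20b, miR-223 and miR-29b in each library of the 4 groups (x axis), with points for libraries and bars for mean ± SD (n = 3). For miR-223 the mean was 2600 CPM in vehicle at 4 h and 420 CPM in vehicle at 24 h; time is confounded with lane block.

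The difference between the 24 h and 4 h responses addresses whether prolonged exposure changes the response to insulin. Values above 0, meaning a higher response at 24 h, included miR-378 at 0.39 (SE 0.22), miR-20a+miR-20b at 0.54 (SE 0.30), miR-26b at 0.43 (SE 0.25), miR-185 at 0.72 (SE 0.43) and miR-136 at 0.53 (SE 0.34). The counts of miR-185 were near background, above the negative control threshold in 1 of 6 libraries at 4 h and 2 of 6 at 24 h. Values below 0 included miR-490 at -0.47 (SE 0.28), miR-26a at -0.40 (SE 0.25), miR-103 at -0.55 (SE 0.38), miR-3471 at -0.45 (SE 0.31) and miR-24 at -0.36 (SE 0.26). For miR-1983 the difference was 0.36 (SE 0.27). None of these passed the test. The Sfmbt2 families lay below 0 for 4 of 5 members (miR-297c -0.62, miR-466d-3p -0.32), with a camera p of 0.0124 (p = 0.109 with an estimated correlation). Neuron-enriched miRNAs lay above 0 for 9 of 13 (miR-132 0.34, miR-218 0.33), but for 0 with housekeeping scaling. The let-7/miR-98 family lay above 0 for 4 of 9 (miR-98 0.50, let-7d 0.27), the miR-17-92 clusters for 3 of 8 (miR-20a+miR-20b 0.54, miR-18a -0.30) and the insulin regulators for 13 of 29 (miR-378 0.39, miR-103 -0.55). Stimulus-responsive miRNAs lay above 0 for 9 of 15 (miR-181a 0.32, miR-34b-5p 0.33), the Dlk1-Dio3 cluster for 6 of 11 (miR-136 0.53, miR-409-5p 0.47), the epithelial list for 1 of 4 (miR-96 -0.18, miR-200b 0.16), the glial list for 4 of 8 (miR-27a 0.29, miR-143 -0.27) and the blood list for 4 of 6 (miR-206 0.42, miR-133a 0.37). Each of these had 0 to 2 members above 0 with housekeeping scaling. The lists' adjusted camera p values ran from 0.267 to 0.927 (adjusted p = 0.954 with an estimated correlation and 0.996 by fry), and 0 members passed when adjusted over the list alone. In edgeR 0 of 195 miRNAs passed, with a smallest adjusted p of 0.991 and 0 at an unadjusted p under 0.05. DESeq2 and limma on the authors' signals called 0, also with 0 at an unadjusted p under 0.05. In the log2 CPM fit, the median of the let-7 family (-0.03) was below 0 and its camera direction above it. Across miRNAs, which are not independent replicates, the responses at 4 h and 24 h correlated with r of 0.23, and 113 of 195 had the same sign. Without insulin 24 h replicate 1, the Sfmbt2 families were called lower for the difference (median -0.34 in the log2 CPM fit, where it was -0.22 with all libraries; adjusted camera p = 0.00467, adjusted p = 0.300 with an estimated correlation). Their adjusted p for the difference ran from 0.00177 to 0.996.

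Averaged over both times, insulin minus vehicle values were 0.36 (SE 0.14) for miR-1983, 0.33 (SE 0.13) for miR-193, 0.27 (SE 0.12) for miR-324-5p, 0.45 (SE 0.19) for miR-409-5p and 0.32 (SE 0.15) for miR-132. Below 0 were miR-421 at -0.30 (SE 0.10), which had the smallest p, miR-33 at -0.24 (SE 0.11), miR-3472 at -0.26 (SE 0.14), miR-193b at -0.24 (SE 0.14) and miR-345-5p at -0.24 (SE 0.14). None of these passed the test. In edgeR 0 of 195 miRNAs passed, with a smallest adjusted p of 0.999 and 6 at an unadjusted p under 0.05; DESeq2 called 0 (7) and limma on the authors' signals 0 (2). In counts with background included, the interval excluded a 2-fold change for 193 miRNAs and a 1.5-fold change for 164.

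The comparison of 24 h with 4 h in vehicle covers culture time without insulin, but it cannot be told apart from lane block. Largest in size was miR-223, a miRNA best known from myeloid cells, at 2600 ± 2120 CPM at 4 h and 420 ± 353 CPM at 24 h, a log2 change of -2.67 (SE 0.71). In the pair of replicate 1 it was at 582 CPM at 4 h and 828 CPM at 24 h, so the direction held in 2 of 3 pairs of the same number. Values above 0 were 1.36 (SE 0.37) for miR-29b, 0.69 (SE 0.19) for miR-221, 0.80 (SE 0.25) for miR-106a+miR-17, 0.71 (SE 0.23) for miR-423-5p and 1.01 (SE 0.34) for miR-296-5p. Values below 0 were also found for miR-328 at -0.77 (SE 0.26), miR-181a at -0.50 (SE 0.17), miR-335-3p at -0.58 (SE 0.20) and miR-136 at -0.72 (SE 0.24). The let-7 family lay above 0 for 7 of 9 members under each scaling tried (let-7e 0.78, let-7d 0.53). None of these passed the test. In edgeR 0 of 195 miRNAs passed, with a smallest adjusted p of 0.143 and 31 at an unadjusted p under 0.05. DESeq2 called 18 (37 at an unadjusted p under 0.05), and limma on the authors' signals called 0 (38). Without vehicle 4 h replicate 3, edgeR called 12; with scaling to the 100 most abundant miRNAs it called 9, and with a mean count of at least 100 it called 7.

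In insulin, 7 miRNAs differed between 24 h and 4 h. Each differed the same way in 3 of 3 pairs of the same number, which adds no separate support because the calls came from the same libraries. Lower at 24 h were miR-26a at -0.91 (SE 0.18, adjusted p = 0.0254), miR-223 at -2.90 (SE 0.74), miR-345-3p at -0.998 (SE 0.26) and miR-335-3p at -0.77 (SE 0.20). Higher were miR-20a+miR-20b at 0.99 (SE 0.21, adjusted p = 0.0351), miR-29c at 0.76 (SE 0.20) and miR-804 at 0.77 (SE 0.20); the other 5 of the 7 had an adjusted p of 0.0469. In CPM, miR-26a was at 1906 ± 197 at 4 h and 1010 ± 166 at 24 h, and miR-223 at 2339 ± 764 and 340 ± 306. Counts of miR-223 exceeded the negative control threshold in 6 of 6 libraries at 4 h and 2 of 6 at 24 h, so its level at 24 h is near background in most libraries and the size of its change is uncertain. With the background subtracted, 2 of the 7 were called in insulin, and miR-223, miR-29c, miR-335-3p, miR-345-3p and miR-804 were not. Of these, miR-335-3p exceeded the threshold in 4 of 6 libraries at 24 h and miR-804 in 3 of 6 at 4 h. Below the threshold for a call were miR-1983 at 0.67 (SE 0.19, adjusted p = 0.0752), miR-185 at 1.05 (SE 0.30), miR-350 at 0.65 (SE 0.19), miR-106a+miR-17 at 0.85 (SE 0.25) and miR-29b at 1.14 (SE 0.37). Of these, miR-185 was near background, above the negative control threshold in 1 of 6 libraries at 4 h and 2 of 6 at 24 h. Values below 0 that were not called included miR-96 at -0.53 (SE 0.16), miR-145 at -0.55 (SE 0.17), miR-3471 at -0.61 (SE 0.22), miR-140 at -0.52 (SE 0.19) and miR-183 at -0.45 (SE 0.17). The 7 calls are not shown to depend on insulin, since the difference between responses gave 0 calls; across miRNAs the time differences in vehicle and in insulin correlated with r of 0.84 and 141 of 195 had the same sign. With a lane covariate edgeR called 0: miR-26a moved from -0.91 (SE 0.18) to -1.15 (SE 0.30), where the SE grew, and miR-345-3p from -0.998 (SE 0.26) to -0.24 (SE 0.33), where the value shrank. With housekeeping scaling 16 were called, 0 of them higher, so the 3 higher calls were lost and the 4 lower ones kept; DESeq2 called 22 and limma on the authors' signals 0 (9 with a pseudocount of 10). The count was 0 without any 1 of insulin 4 h replicate 1, insulin 4 h replicate 2, insulin 24 h replicate 2, vehicle 24 h replicate 2 or vehicle 24 h replicate 3; it was 1 without insulin 24 h replicate 3, 3 without vehicle 4 h replicate 1 or replicate 2, 4 without vehicle 24 h replicate 1, 11 without insulin 4 h replicate 3 and 22 without insulin 24 h replicate 1.

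Averaged over both treatments, a comparison added after the data were seen, 24 h and 4 h differed for 30 miRNAs, 19 higher and 11 lower at 24 h. Among those higher at 24 h were miR-29b at 1.25 (SE 0.26), miR-31 at 1.03 (SE 0.27), miR-296-5p at 1.03 (SE 0.24), miR-322 at 1.02 (SE 0.29) and miR-16 at 0.94 (SE 0.27). Among those lower were miR-223 at -2.78 (SE 0.51), miR-291b-3p at -1.15 (SE 0.34), miR-345-3p at -0.84 (SE 0.18), miR-26a at -0.71 (SE 0.12) and miR-335-3p at -0.68 (SE 0.14). Near background at 24 h were miR-223, miR-291b-3p, miR-126-3p and miR-185, above the threshold in 2, 1, 0 and 2 of 6 libraries, so the size of their change is uncertain. There miR-291b-3p had 20 to 45 counts. At 4 h miR-291b-3p exceeded the threshold in 2 and miR-185 in 1 of 6 libraries, so both were near background at both times. With the background subtracted 28 were called, and miR-291b-3p, miR-322, miR-1983, miR-185 and miR-709 were not. Abundant miR-29b went from 30289 ± 15895 CPM in vehicle at 4 h to 77686 ± 9627 CPM at 24 h, and from 36967 ± 16416 to 81632 ± 12125 CPM in insulin. Of the let-7 family, let-7e (0.72, SE 0.19) and let-7d (0.67, SE 0.19) passed among the 9 members, and of the miR-17-92 clusters miR-20a+miR-20b (0.72), miR-106a+miR-17 (0.82) and miR-93 (0.54) among the 8. Of the 29 insulin regulators 9 passed, among them miR-1983 at 0.49 (SE 0.14), miR-29c at 0.66 (SE 0.14), miR-221 at 0.63 (SE 0.13) and miR-145 at -0.53 (SE 0.12). Of the other lists, 4 of 15 stimulus-responsive, 2 of 4 epithelial (miR-96 -0.44, miR-183 -0.42), 2 of 8 glial and mesenchymal (miR-145 -0.53, miR-140 -0.46) and 2 of 6 blood (miR-223, miR-126-3p -0.44) members passed, and 0 of the neuron-enriched, Dlk1-Dio3 and Sfmbt2 members. As sets, the lists did not pass in any of the 3 time comparisons (smallest adjusted camera p = 0.0890, for the miR-17-92 clusters in vehicle; adjusted p = 0.678 with an estimated correlation). The smallest adjusted p over miRNAs was 0.00726, and 54 had an unadjusted p under 0.05; DESeq2 called 41. With a lane covariate 0 were called, and the values of miR-31, miR-296-5p, miR-322 and miR-16 turned below 0. There miR-29b moved from 1.25 (SE 0.26) to 0.08 (SE 0.37) and miR-26a from -0.71 (SE 0.12) to -0.94 (SE 0.27). With housekeeping scaling 17 were called, 0 of them higher; the count was 12 without vehicle 24 h replicate 2 or vehicle 24 h replicate 3, 15 without insulin 4 h replicate 2, 16 without insulin 24 h replicate 2, 19 without vehicle 4 h replicate 1 and 52 without insulin 24 h replicate 1.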

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

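The cross-reaction test was chosen after the result was seen. Probes for viral miRNAs, which the cells should lack and which took no part in the comparisons, exceeded the negative control threshold for 33 of 396 values. The mghv-miR-M1-5 probe did so in 12 of 12 libraries (42 to 227 counts, at most 2.23 times the threshold). The mcmv-miR-m01-2 probe did so in 5 libraries (30 to 111 counts), mcmv-miR-m01-3 in 3 (24 to 108 counts) and mghv-miR-M1-4 in 3 (39 to 77 counts). In all, 5 of the 33 viral probes exceeded the threshold in at least 3 of 12 libraries, the filter used for the tested mouse miRNAs. Some tested miRNAs with counts near the threshold may therefore have passed the filter without their target being present.

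The mghv-miR-M1-9 probe exceeded the threshold in 5 libraries, with 33 to 130 counts at 4 h and 18 to 43 at 24 h. Over the 6 libraries of 4 h its log2 counts correlated with those of miR-223 (r = 0.95, exact permutation p = 0.00417, adjusted p = 0.00833 over 2 relations; rho = 0.94, exact permutation p = 0.0167; two-sided), and r was 0.73 without the 2 libraries farthest from the median and 0.93 after scaling by library size (exact permutation p = 0.0153). Over the 6 libraries of 24 h r was 0.27 (exact permutation p = 0.624; rho = 0.26), and 0.71 after scaling by library size (exact permutation p = 0.0889). Cross-reaction with the target of the miR-223 probe may account for the signal at 4 h, while background or another shared source stays open. No biological explanation was tested.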

How the results depend on the processing

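The lane covariate, leaving out the pair of libraries of lowest mean r with their group (insulin 24 h replicate 1 and vehicle 4 h replicate 1, with vehicle 4 h replicate 3 close), and the time contrast averaged over treatments were chosen after the data were seen. The insulin contrasts and their difference had 0 calls under each alternative run (edgeR, DESeq2 and limma); the smallest adjusted p ran from 0.136 to 1.000 at 24 h. For 24 h against 4 h in vehicle (0 calls), counts were 18 with DESeq2, 9 with scaling to the 100 most abundant miRNAs, 1 with positive controls, 7 with a mean count of at least 100, 1 without that pair and 0 to 12 leaving out 1 library. In insulin (7) they were 22 with DESeq2, 15 with the 100 most abundant, 16 with housekeeping scaling, 2 with positive controls, 2 after background subtraction, 1 with no filter, 13 with a mean count of at least 100, 0 and 9 with limma on signals at a pseudocount of 1 and 10, 2 with only the compared groups, 0 with the lane covariate, 38 without that pair and 0 to 22 leaving out 1 library. Averaged (30), they were 17 with housekeeping and 17 with positive control scaling, 9 with no filter, 0 with the lane covariate and 12 to 52 leaving out 1 library. The lane covariate turned miR-296-5p to -0.17, miR-31 to -0.12, miR-322 to -0.34 and miR-16 to -0.22. Fewer libraries, and more probes to adjust for with no filter, account for some of this; otherwise the cause was not tested. List calls (0) were 2 without that pair, both of the Sfmbt2 families (adjusted p = 0.479 with an estimated correlation and 0.737 by fry), and 0 to 2 leaving out 1 library (adjusted p of at least 0.300 with an estimated correlation and 0.505 by fry). With the replicate number as a block, counts were 10 in vehicle and 18 in insulin. Across time, same-numbered libraries had r of -0.03, -0.21 and 0.09 in vehicle, and -0.07, 0.21 and -0.35 in insulin. For insulin against vehicle at 24 h and elsewhere the block changed no call count by over 1.5 times. The block gives each number the same effect at both times, so it did not test pairing within 24 h alone. Relative to TMM, housekeeping scaling shifted the median of all miRNAs by -0.39 at 24 h, -0.18 for time in vehicle, -0.56 for time in insulin and -0.37 averaged; the 100 most abundant shifted it by -0.11 at 4 h. Of 2368 values of named miRNAs under alternatives, 2076 kept their direction and side of the threshold, 140 lost and 85 gained a call, 63 uncalled ones changed sign and 4 reversed.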

Other observations

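The tests of blood cell RNA, probe background and swapped labels, the simulated lane drift, the splits that keep pairs together and the housekeeping mRNA values were chosen after the data were seen. Relative to the miRNAs, ribosomal protein mRNA Rpl19 was at 20396 CPM with insulin at 4 h and 42543 CPM at 24 h, a log2 difference of 1.06 (SE 0.21, adjusted p = 0.0133 in edgeR). In vehicle the difference was 0.26 (SE 0.20, adjusted p = 0.591), and the difference between treatments did not pass (0.80, SE 0.29, adjusted p = 0.991). For Actb the values were 0.78 (SE 0.22) in insulin and 0.35 (SE 0.22) in vehicle. Averaged over treatments, Rpl19 (0.66, SE 0.15, adjusted p = 0.00784 in edgeR) and Actb (0.56, SE 0.15, adjusted p = 0.0264) passed. Gapdh (0.41, SE 0.22, adjusted p = 0.238 in edgeR) and B2m (0.01, SE 0.21, adjusted p = 0.979) did not. At 24 h the insulin minus vehicle value was 0.77 (SE 0.21, adjusted p = 0.400) for Rpl19, 0.51 (SE 0.22) for Actb, 0.24 (SE 0.31) for Gapdh and 0.22 (SE 0.29) for B2m.

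For a trend with lane, and so with replicate number, within each time point, 33 of 195 miRNAs had an unadjusted p under 0.05 in edgeR, and 3 passed adjustment (miR-876-5p -0.35 per lane, miR-322 0.25 and miR-296-5p 0.21). Abundant miR-29b (0.21, adjusted p = 0.0944), miR-16 (0.22, adjusted p = 0.134) and let-7c (0.20, adjusted p = 0.149) did not. A lane effect nominally predicts that insulin minus vehicle values of the 33, 1 lane apart, follow the trend with a slope of 1. A difference between the 3 repeats predicts 0. The slope was 0.80, with a 95% interval of 0.41 to 1.20 over miRNAs. From the spread between libraries left after the lane trend was fitted, the interval was -1.02 to 2.62. The 2 explanations cannot be told apart with 12 libraries. For the 24 h minus 4 h values, a continued drift over 6 lanes nominally predicts 6 and none predicts 0. The slope was 3.10 (interval 2.31 to 3.92 over miRNAs, 1.28 to 4.92 from the same spread between libraries). That spread leaves out the lane trend, so its intervals are too narrow if the trend is a difference between repeats. The intervals therefore do not decide about 0 or 6. In 100 simulated sets with full drift, the same selection and fitted trends scaled by 0.784 or 0.615 for their error, the median slope was 3.87 (range 2.87 to 5.10) or 3.20 (1.89 to 4.20) rather than 6, so lane drift may account for part or all of these values, and a change over culture time stays open. The slope expected over 1 lane for insulin minus vehicle may lie below 1 for the same reason, but it was not simulated.

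The decrease of miR-223 from 4 h to 24 h was set against technical explanations. RNA from mixed blood cells would bring miR-142-3p, miR-150, miR-144, miR-451 and miR-486, but 0 of their 30 values at 4 h exceeded the threshold (5 to 62 counts, against 92 to 832 for miR-223). A source of myeloid cells alone need not bring all 5 of these, so the counts do not decide about it. Background shared with the negative controls would leave miR-223 at the threshold, but 6 of 6 libraries at 4 h exceeded it. The viral mghv-miR-M1-5 probe also did so in 6 of 6 (99 to 156 counts), so background of a single probe is not excluded. Swapped time labels of vehicle replicate 1 would turn other miRNAs called without its libraries. In that pair 15 of 15 kept their direction (interval 78.2% to 100%, treating miRNAs as independent). Lane drift could keep that direction even after a swap, so the test does not decide about one. Serum RNA, whose make-up was not measured, stays open: the other 5 tested members of the blood list had a median of 0.21 (SD 0.33, range -0.44 to 0.37), but their 39 to 94 counts at 4 h, each above the threshold in 2 to 5 of 6 libraries, were too near background to show a decrease as large. Lane block stays open as well, beside a change over culture time: with a 24 h level near background, the value was -1.30 (SE 0.82) after a lane covariate against -2.78 (SE 0.51) before.

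Other splits of the libraries were counted for each comparison. For 24 h against 4 h averaged over treatments, 1 of 100 splits, the real one, gave 30 calls and the highest other gave 6. However, same-numbered vehicle and insulin libraries of 24 h may be paired, so this share does not decide about chance. Of the 10 splits that keep such libraries together, 1 gave as many and the highest other gave 6, and 10 splits are too few for a share under 0.05. For time in insulin, 1 of 10 splits gave as many as the real 7 and the highest other gave 0; for time in vehicle 10 of 10 gave as many as the real 0 and the highest other 0, with 10 splits again too few. The same limit holds for insulin at 24 h (real 0, highest other 0, 10 of 10, so splits that part as many same-numbered pairs gave 0 too) and at 4 h (real 0, highest other 31, 10 of 10). That split of 31 set lanes 1 to 3 against lanes 4 to 6, which points to a structure of the libraries along lane and replicate number; for insulin at 4 h the count was 0 with a replicate block and 0 with a lane covariate. For the difference between responses and for insulin averaged over times, 100 of 100 splits gave as many as the real 0 and the highest other was 40 for each. Where the real count is 0 no split can give fewer, so those counts decide nothing about chance.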
